A study of Arabidopsis thaliana with 4 samples.

How the data were processed

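TAIL-seq libraries were made by the submitters from total RNA of seedlings of 4 genotypes, grown for 2 weeks on soil under 16 h light and 8 h darkness per the labels' protocols. Per the submitters' processing notes, the tools included CASAVA 1.8.2, TopHat2 2.0.9, Bowtie2 and bedtools 2.17.5, and the genome build was TAIR10; how each was used is not given in the sources used here. The deposited table has 1 line per read and, per the file headers, gives the read identifier, the genotype, the length of the A tract, the added nucleotides and their number, the length of both together, a category for the 3′ end and the gene locus. It gives tract lengths in nucleotides and no normalised value. On the file, A tracts ran from 4 to 30 nt, the stated sizes fitted the stated bases on every line, and no read identifier occurred more than once. How reads were filtered, how tails were measured and why the range ends at 30 A is not given in the sources used here, so the totals per library are those of short tails and not full library depth. The genotype column names the double mutant by 2 initials (UX); this was taken as urt1 xrn4 because the other 3 names equal the labels of the other libraries. The labels give 1 library per genotype.

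A tail was called uridylated where the table's category was a U extension. All 13708 such extensions contained only U and A, and 2457 of them were written with A first. The direction in which extensions are written is not stated, so only their composition and number of U were used. All reads were counted; 0 were from organelle genes. Gene symbols and products came from NCBI's annotation of TAIR10.1, where 8310 of 8346 loci were matched. This reference was used for names and for the check of genome-encoded A runs only. No coordinates are printed because the builds differ in name. Genes of near-identical families, such as CAB1, CAB2 and CAB3, can share reads.

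All values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Shares per library have exact Clopper-Pearson 95% intervals and 95% intervals from 1000 bootstrap samples of genes; the latter are printed unless stated. A count of 0 allows 3 counts of the total. Reads carry no molecular identifiers, and repeated reads were frequent: distinct combinations of gene, A length and extension were 64.2% of reads in WT, 47.1% in urt1, 58.7% in xrn4 and 50.0% in urt1 xrn4. In WT genes with few reads, 37.1% of read pairs within a gene were identical against 1.97% of pairs drawn over these genes, so intervals that cover counting error only are too narrow. Tail length was described by medians and means of the A tract and by the classes 4 to 9, 10 to 25 and 26 to 30 A.

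Uridylation per gene was compared over genes with at least 50 tails in both libraries, with Newcombe's 95% interval of the difference. Share of reads per gene was compared as the log2 ratio of counts scaled to the table's reads per library (CPM) with 0.5 added to each count and an exact conditional binomial 95% interval, over genes with at least 20 reads in the 2 libraries together. A gene was counted where the ratio was at least 2 in either direction and the interval excluded 1. Where 1 library is deeper, this minimum lets in more easily genes with the higher share of reads there. The split into higher and lower genes is therefore not read as a direction. For a gene with 0 reads in 1 library, the fold was computed against 3 reads there and given as a lower bound; with such bounds the counts in either direction together were 107, 41, 117, 137 and 134 for the 5 comparisons in place of 124, 41, 117, 137 and 134. Mean A length per gene was compared over genes with at least 20 tails in each library. Fisher's exact test compared reads of 2 libraries and not genotypes, and no p-value across genes was computed. Comparisons were urt1 with WT, xrn4 with WT, and urt1 xrn4 with WT, xrn4 and urt1. The 3 comparisons with WT share 1 library, and their chance values are therefore shared too.

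The genes named were set by a rule written before the data were examined: URT1, HESO1, XRN4, up to 4 members of each gene list with the most reads, and per comparison the 10 genes higher and 10 lower whose interval lay farthest from no change, for share of reads and for uridylation. For tail length it took the 5 genes with the largest increase and the 5 with the largest decrease among those with at least 100 tails in each library. The text gives those of main interest. The 14 gene lists (250 genes) were fixed at the same time. A list with at least 3 tested members was described by its median log2 ratio and by its pooled uridylation, each placed among 10000 random lists of the same size matched on mean expression in 10 bins. These percentiles describe these libraries only.

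The per-gene steps were tested on simulated reads with the real genes, library sizes and up to 200 changed genes. For urt1 against WT (443 genes in the step) 38.7% of 2-fold, 93.5% of 4-fold and 100% of 8-fold changes were recovered, 0 in the wrong direction, and 6 of 269 genes with no change passed. For xrn4 against WT (147 genes) 45.5%, 95.7% and 100% were recovered, and 5 of 83 genes with no change passed. The simulation draws independent reads. A further null assigned whole sets of identical reads to the 2 libraries at random in 100 draws. Such a set can also hold different molecules with the same A length and extension. This null can therefore overstate what copies alone give, more so in genes with many reads.

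Alternatives covered the read and gene sets used for shares, length classes, minimum tails and reads, the added count, the fold, thinning to the shallower library, TMM and median of ratios scaling, bins of the random lists and the scale of additivity. Counting identical reads once, using each of the 2 sequencing lanes alone, rescaling the gene lists and leaving out each list member in turn were chosen after the data were examined.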

Results

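The series profiled the 3′ ends of mRNAs from 2-week-old Arabidopsis thaliana seedlings by TAIL-seq, a method that ligates an adapter to RNA 3′ ends and reads the poly(A) tract together with any nucleotides added after it. There were 4 libraries, 1 per genotype: wild type (WT), the mutants urt1-1 and xrn4-3 (urt1 and xrn4 below) and the urt1-1 xrn4-3 double mutant (urt1 xrn4). URT1 is a terminal uridylyltransferase that adds uridines to mRNA 3′ ends, and XRN4 is the main cytoplasmic 5′-to-3′ exoribonuclease of plants. The table held reads on 8346 genes: 10304 from WT, 43391 from urt1, 9797 from xrn4 and 26300 from urt1 xrn4. Each read carried an A tract of 4 to 30 nt and was classed as unmodified or as carrying a U, G or C extension. Longer tails were not analysed here, so a gene's share of reads is its share of short-tailed 3′ ends and not its mRNA level. With 1 library per genotype there is no replicate check on any difference. Percentages carry 95% intervals from resampling genes within a library (gene bootstrap) or, where stated, exact Clopper-Pearson intervals, and both cover sampling of reads or genes only.

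The targeted genes were looked at first. No read of URT1 (AT2G45620), of XRN4 (AT1G54490) or of HESO1 (AT2G39740), the second known uridylyltransferase acting on plant RNAs, was present in any of the 4 libraries. A count of 0 allows up to 291 CPM (counts scaled to a common library total) in WT, 69.1 in urt1, 306 in xrn4 and 114 in urt1 xrn4. The reads therefore could not check the genotype labels through these transcripts.

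The comparison of urt1 with WT asks how much of mRNA uridylation depends on URT1. Uridylated tails made up 31.7% of WT tails (3268 of 10304; 29.7 to 33.9) and 6.87% of urt1 tails (2983 of 43391; 6.39 to 7.38), a 4.61-fold lower share, with a difference of -24.8 percentage points (-27.1 to -22.9). With identical reads counted once the shares were 28.4% and 10.4%. That counting also merges different molecules with the same A length and extension, more so in the deeper urt1 library. At gene level the share was lower in urt1 for 15 of the 16 genes with at least 50 tails in both libraries, and the interval of the difference lay below 0 for 10 of them. LHCB2.2 (AT2G05070), a light-harvesting protein of photosystem II, had 44.7% uridylated tails in WT (46 of 103) and 6.36% in urt1 (25 of 393). PSAG (AT1G55670), a subunit of photosystem I, had 19.6% and 2.02%, and AT2G45180, a lipid-transfer family protein, had 18.2% and 1.57%. Transcripts of the translation machinery were among the 10 as well. AT5G56710 (ribosomal protein L31e) had 7 of 50 tails uridylated in WT and 1 of 306 in urt1. AT1G07940 (an elongation factor of the Tu family) had 24.2% and 9.77%, and AT3G09200 (ribosomal protein L10 family) 13.8% and 3.18%. The others were FBA2 (AT4G38970), a plastid fructose-bisphosphate aldolase, with 13.5% and 6.49%, RBCS1A (AT1G67090), a Rubisco small subunit, with 8.80% and 3.43%, LHCB2.1 (AT2G05100) with 23.8% and 12.5%, and CAB1 (AT1G29930) with 12 of 68 tails and 39 of 420. The interval included 0 for the other 6 genes, named after their values were seen. RCA (AT2G39730), the Rubisco activase, had 29.9% in WT (52 of 174; exact 23.2 to 37.3) and 25.7% in urt1 (87 of 339; exact 21.1 to 30.7), LHCB6 (AT1G15820) 12.5% and 8.45%, emb2171 (AT3G04400) 6.25% and 2.92%, the plastocyanin gene DRT112 (AT1G20340) 9 of 92 tails and 36 of 514, and CAB3 (AT1G29910) 8.43% and 6.77%. CRD1 (AT3G56940), a chlorophyll synthesis enzyme, was the 1 gene with the higher share in urt1 (16.7% against 11.8%). CAB1 and its near-identical neighbours CAB2 and CAB3 can share reads, so their values are uncertain. Whole sets of identical reads (same gene, A length and extension) were also assigned to the 2 libraries at random. In 100 draws this gave 5.48 genes with an interval on either side of 0 on average and up to 11, against the 10 observed. The draws did not count the 2 sides apart, so 10 below 0 and 0 above was not set against chance.

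**Figure D1:**
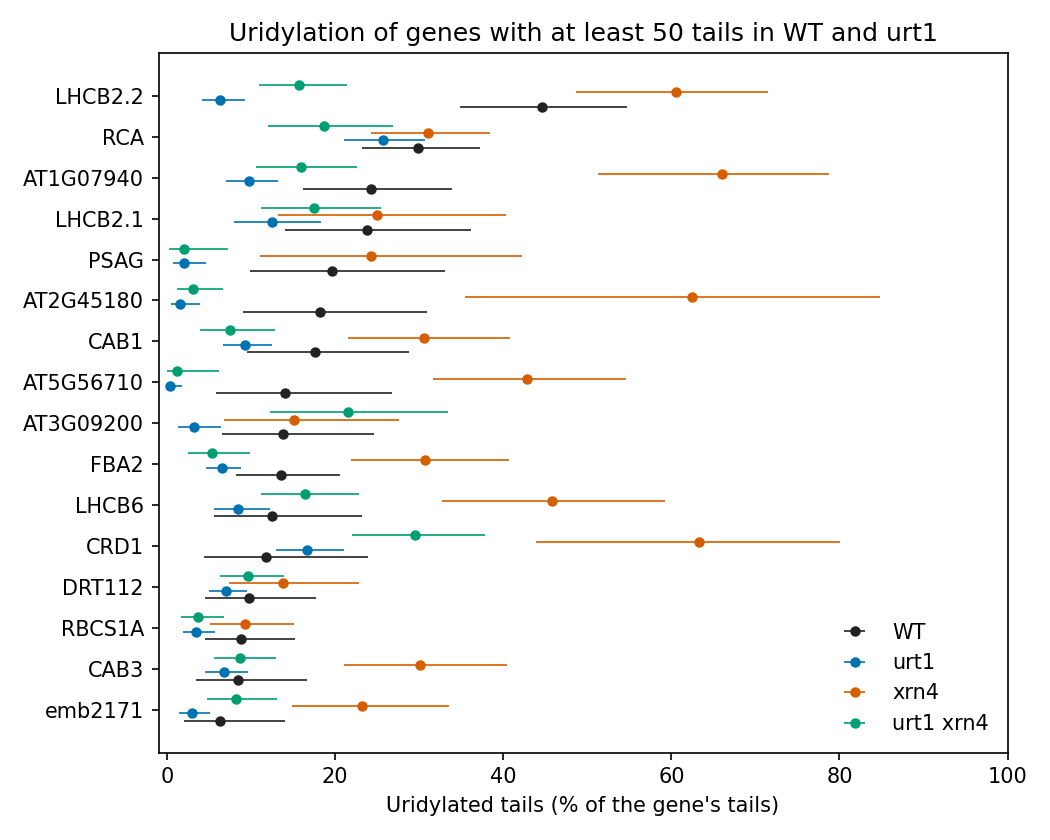
Share of uridylated tails (x axis, percent of the gene's tails) of the 16 genes with at least 50 tails in both WT and urt1, ordered by the WT share; points are the 4 libraries (1 each) and bars are exact 95% binomial intervals. LHCB2.2 went from 44.7% in WT to 6.36% in urt1 and stood at 60.5% in xrn4, while RCA lay at 25.7% in urt1 against 29.9% in WT.

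Uridylation in WT varied with A length, with 37.9% of tails of 4 to 9 A and 32.5% of tails of 10 to 25 A. It peaked at 11 A, where 73.3% of tails (307 of 419; exact 68.8 to 77.4) carried U, and was 7.27% for tails of 26 to 30 A. In urt1 the share at 11 A was 11.2%, a small local maximum between 8.87% at 8 A and 8.65% at 13 A, and the highest share was 17.8%, at 4 A. Unmodified tails of the same length were more frequent in urt1: tails of 11 A made up 3.85% of unmodified tails there and 1.39% in WT. The most frequent unmodified tail had 16 A in all 4 libraries. Uridylated WT tails had a median of 13 A, and 15 nt when the added nucleotides were counted. Among genes with at least 20 tails in both libraries, mean A length was shorter in urt1 for 38 of 58, with a median difference of -0.84 nt. The 4 genes with at least 100 tails in each were LHCB2.2 (14.4 A in urt1, 16.1 in WT; SE of the difference over reads 0.575 nt), RCA (16.0 and 16.9; SE 0.609), FBA2 (15.6 and 16.0; SE 0.600) and RBCS1A (0.406 nt longer in urt1; SE 0.709).

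**Figure D2:**
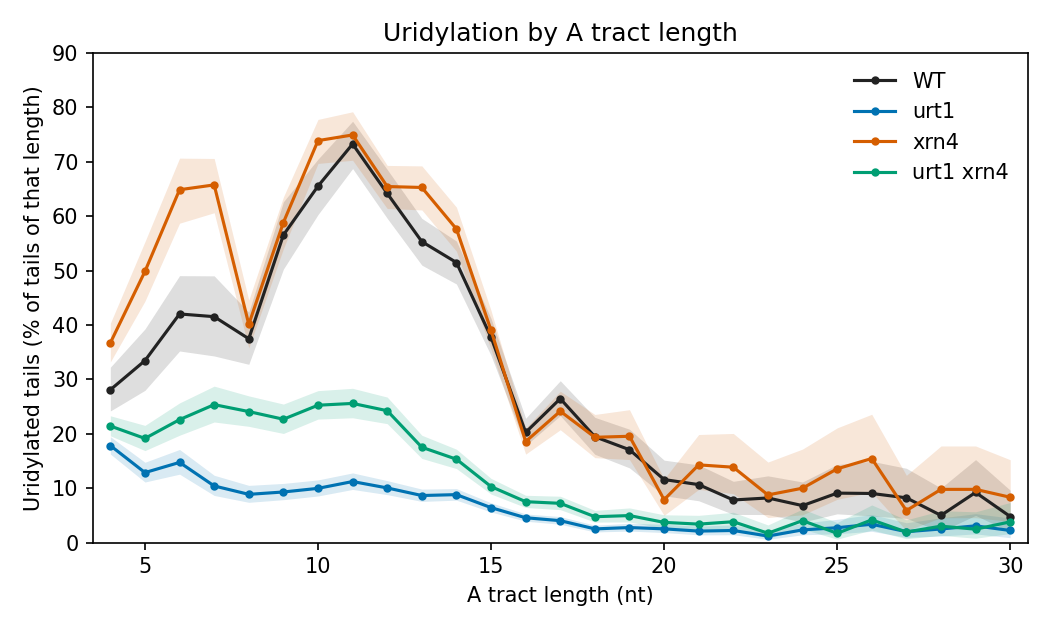
Uridylated tails as a percent of all tails of each A length (y axis) against A tract length in nt (x axis) for the 4 libraries (1 each); shaded bands are exact 95% binomial intervals. WT and xrn4 reach 73.3% and 74.9% at 11 A, and urt1 stays at or below 17.8%.

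**Figure D3:**
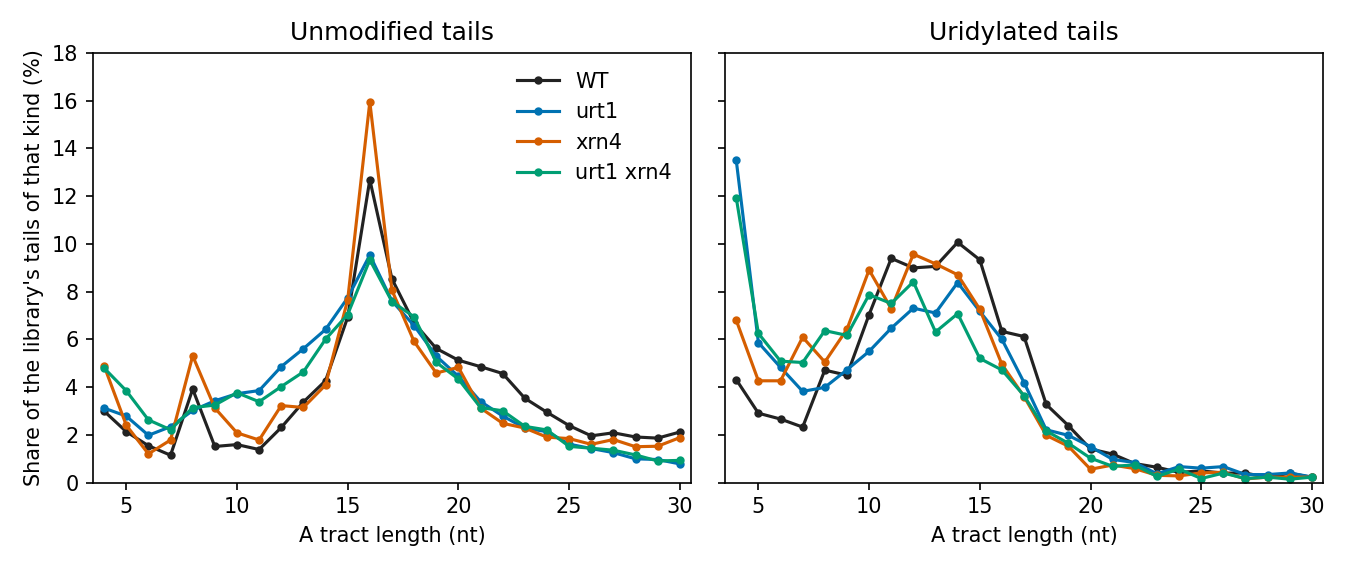
Distribution of A tract lengths (x axis, nt) of unmodified tails (left) and uridylated tails (right) as a percent of each library's tails of that kind (y axis), 1 line per library. Unmodified tails have their mode at 16 A in all 4 libraries, and at 11 A they make up 1.39% in WT and 3.85% in urt1.

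The extensions that remained in urt1 were shorter. In WT 32.8% of uridylated tails held 1 U (29.7 to 36.0), 46.1% held 2 and 21.2% held 3 or more. In urt1 69.4% held 1 U (66.3 to 72.6), 22.0% held 2 and 8.68% held 3 or more. Extensions made of both U and A were 29.3% of uridylated tails in urt1 and 13.1% in WT, a difference of 16.2 points (13.1 to 19.2).

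**Figure D4:**
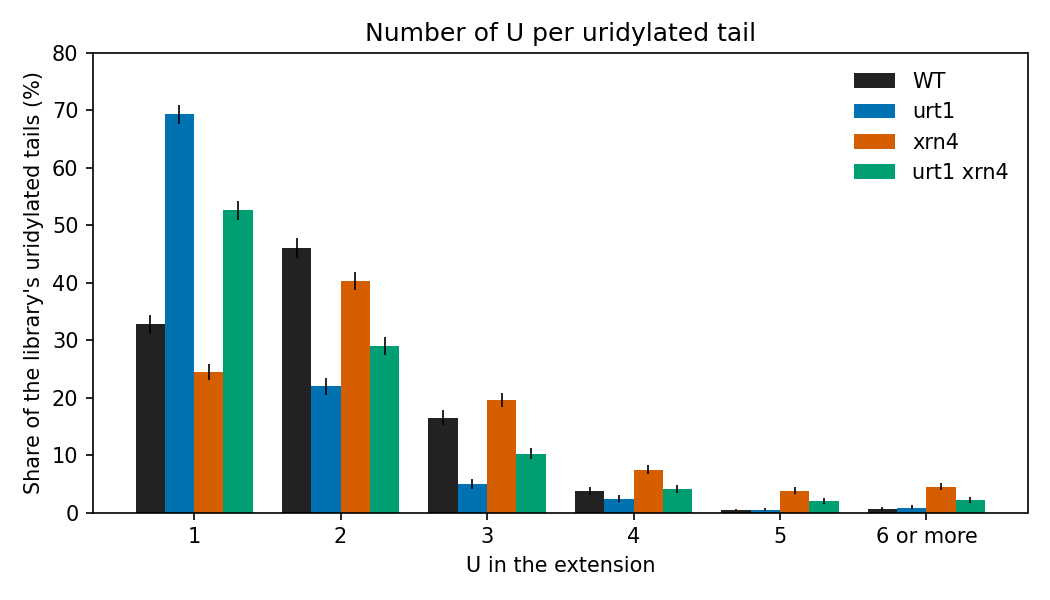
Share of each library's uridylated tails (y axis, percent) by the number of U in the extension (x axis); bars are the 4 libraries (1 each) with exact 95% binomial intervals. Tails with 2 U were the largest class in WT (46.1%) and xrn4 (40.3%), and tails with 1 U in urt1 (69.4%) and urt1 xrn4 (52.6%).

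Of the gene groups fixed before the data were examined, the 3 with enough reads had lower uridylation in urt1. Pooled over members, photosystem and light-harvesting transcripts had 20.5% uridylated tails in WT and 7.44% in urt1, Calvin cycle transcripts 21.4% and 10%, and cytosolic ribosomal protein transcripts 21.5% and 3.27%. Over members read in both libraries these differences lay at percentiles 90.6, 87.8 and 60.5 of random lists matched on read number, inside the central 95%. In share of reads, the ribosomal protein group stood apart. Its 21 members with at least 20 reads had a median log2 ratio of 1.16 in urt1 over WT, at percentile 99.8 of random lists, while the median of all 440 genes tested was 0.31. Of these members 9 were at least 2-fold higher with an interval that excluded no change and 0 were lower. RPS15A (AT1G07770) had 2189 CPM in urt1 and 679 in WT (95 and 7 reads). SAC52 (AT1G14320, ribosomal protein L16p/L10e family) had 5877 and 2717 (255 and 28 reads). AT3G09200 had 5070 and 6308 CPM and emb2386 (AT1G02780, ribosomal protein L19) 2650 and 4755. With both other scalings the median stayed above 0, at 1.98 with TMM and at 0.91 with median of ratios (6 higher, 1 lower). It was 0.47 over 11 members with identical reads counted once, at percentile 99.9, and 1 was higher and 1 lower; fewer members and reads were left to test. The 38 photosystem members had a median of 0.15 (2 higher, 3 lower) and the 15 Calvin cycle members 0.31 (1 higher, 1 lower). With TMM scaling these 2 medians were 0.96 (17 higher, 0 lower) and 1.13 (7 higher, 0 lower). The photosystem median turned to -0.10 with median of ratios scaling, and with identical reads counted once the 2 medians were -0.38 and -0.63.

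Of the 440 genes, 88 had a share of reads at least 2-fold higher and 36 at least 2-fold lower in urt1 than in WT. CP12-1 (AT2G47400), a regulator of the Calvin cycle, had 225 reads in urt1 and 3 in WT (log2 ratio 3.94, interval 2.59 to 6.44), and XTH4 (AT2G06850), a cell wall enzyme, 75 and 1 (3.58, 1.63 to 9.48). AT3G62530 (80 reads) was at least 6.33-fold higher against 0 reads in WT, AT1G09310 and the ribosomal protein gene AT1G48830 (47 each) at least 3.72-fold, and AT3G24830 (ribosomal protein L13) and AT3G07950 (38 each) at least 3.01-fold. AT5G65220 (ribosomal protein L29) and PFL (AT1G22780, ribosomal protein S18) were higher too, with log2 ratios of 3.19 (1.22 to 9.09) and 2.29. Lower in urt1 were the F-box genes KUF1 (AT1G31350; 3 and 18 reads, log2 ratio -4.48, -7.07 to -2.88) and EBF1 (AT2G25490, which targets the ethylene regulator EIN3; -1.80), SCO1 (AT1G62750, a plastid elongation factor; -2.25), GSTU20 (AT1G78370; -1.68), LAP2 (AT4G30920; -1.82), XYL1 (AT1G68560; -2.07), AT4G29905 (-3.23), AT3G56360 (-2.19), AT4G28240 (-2.14) and AT5G64270 (-2.47). These counts are weak evidence: when sets of identical reads were assigned to the 2 libraries at random, 89.9 genes passed on average and up to 111 in 100 draws, against the 124 observed. TMM scaling, which shifted all log2 ratios by 0.82, gave 199 higher and 10 lower, and median of ratios scaling 59 and 56. The split also turned with identical reads counted once (10 higher, 17 lower; 16 of these 27 genes were among the 124) and with no minimum of reads (97 and 490).

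The comparison of xrn4 with WT asks how loss of the exoribonuclease changes the uridylated pool. Uridylated tails made up 40.2% of xrn4 tails (3939 of 9797; 37.6 to 42.6), 8.49 points above WT (5.24 to 11.6), and all 12 genes with at least 50 tails in both libraries had the higher share in xrn4. The interval excluded 0 for 7 of them. With a minimum of 20 tails (34 genes) it lay above 0 for 14 and below 0 for 4. The single direction thus holds only at the higher minimum. AT1G07940 had 66.0% in xrn4 (33 of 50) and 24.2% in WT, LHCB6, a minor antenna protein of photosystem II, 45.8% and 12.5%, and AT5G56710 42.9% and 14.0%. CAB3 had 30.1% and 8.43%, FBA2 30.7% and 13.5%, emb2171 (ribosomal protein L23) 23.3% and 6.25%, and LHCB2.2 60.5% and 44.7%. Random assignment of sets of identical reads gave 3.41 genes with an interval on either side of 0 on average and up to 9. The 7 observed were all above 0, a split that was not set against chance. The highest uridylation was again at 11 A, with 74.9% of tails (exact 70.3 to 79.2), and the gap to WT was largest in shorter tails: 49.5% of xrn4 tails of 4 to 9 A were uridylated (45.3 to 53.7) and 37.9% in WT (34.4 to 41.8). At the length distribution of WT the xrn4 share was 35.3%. With identical reads counted once, an alternative chosen after the data were examined, the shares were 31.2% in xrn4 and 28.4% in WT, a smaller gap.

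Extensions were longer in xrn4. Tails with 3 or more U made up 35.2% of uridylated tails (31.7 to 38.9) against 21.2% in WT (18.5 to 23.9), the mean was 2.45 U against 1.95, and 4.49% held 6 or more against 0.581%. A tracts were shorter: 26.7% of xrn4 tails had under 10 A (25 to 28.4) and 17.9% of WT tails (16.7 to 19.2). Mean A length was shorter in xrn4 for 29 of 34 genes, with a median difference of -1.86 nt, including RCA (14.0 and 16.9 A; SE 0.665 nt), FBA2 (13.3 and 16.0; SE 0.764) and RBCS1A (15.1 and 17.0; SE 0.847).

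Photosystem transcripts had 30.9% uridylated tails in xrn4 against 20.5% in WT and ribosomal protein transcripts 38.7% against 21.5%. Calvin cycle transcripts had 20.3% and 21.4%, and their difference over members read in both lay at percentile 6.83 of random lists, inside the central 95%. FBA1 (AT2G21330), an aldolase, alone set that direction, with 5 of 45 tails in xrn4 and 22 of 38 in WT: without it, an alternative chosen after the data were examined, the shares were 21.0% and 18.8%. In share of reads no list had a median outside the central 95% of random lists: photosystem members had a median log2 ratio of -0.03 (24 tested, 1 higher, 2 lower; above 0 with TMM scaling, and 0.13 with identical reads counted once), Calvin cycle members 0.18 (7 tested, 0 higher, 0 lower) and ribosomal protein members 0.12 (5 tested, 2 higher, 0 lower; -0.22 over the 3 with at least 50 reads). Of 138 genes tested, 23 were higher and 18 lower. The higher ones included AT4G16141, a GATA-type factor (27 reads against 0, at least 9.47-fold), the translation release factor ERF1-1 (AT5G47880, 23 against 0, at least 8.06-fold), AT5G51970 (24 reads against 1, log2 interval 2.04 to 10.02), AT1G01490 (3.24, 1.76 to 5.80), AT1G13360 (2.76, 1.21 to 5.33), RPL5B (AT5G39740; 2.69, 1.14 to 5.27), CP12-1 (2.62, 1.06 to 5.20), CYP86A2 (AT4G00360; 2.47, 0.88 to 5.06), the methionine synthase MS2 (AT3G03780; 1.87) and AT3G22230, ribosomal protein L27e (28 reads against 7). Lower were PDH-E1 ALPHA (AT1G01090, 0 reads against 26, at least 8.24-fold), the plastid protease subunit CLPP4 (AT5G45390) and AT5G28060 (1 read each against 23; -3.90, -9.82 to -1.83), the ferredoxin FED A (AT1G60950; -3.10, -6.52 to -1.36), EBF1 (-2.67, -5.25 to -1.14), AT2G45180 (-1.68), LHCA3 (AT1G61520; -1.95), RBP47A (AT1G49600; -2.33, -4.92 to -0.74), AT3G18060 (-1.67) and AT4G17390 (-1.72). Random assignment of sets of identical reads gave 26.1 such genes on average and up to 40, against the 41 observed. Counting identical reads once left 3 higher and 2 lower, and a minimum of 50 reads left 0 and 2. Most of the genes named had too few reads or distinct ends to be tested in these settings. Their calls were thus lost there without a test. Several rested on few distinct ends, such as 27 reads with 4 distinct ends for AT4G16141 and 24 with 3 for AT5G51970.

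The double mutant asks whether the uridylation seen without XRN4 needs URT1. Uridylated tails made up 13.4% of urt1 xrn4 tails (3518 of 26300; 12.5 to 14.3), 3.01-fold below xrn4, with a difference of -26.8 points (-29.4 to -24.2), and 1.95-fold above urt1, with a difference of 6.50 points (5.46 to 7.49). Against WT the difference was -18.3 points (-20.7 to -16.1). The gaps to xrn4 and to WT were smaller with identical reads counted once, with the shares given in the part on processing. Against xrn4, 13 of 15 genes had the lower share and 12 an interval below 0: AT1G07940 had 15.9% against 66.0%, LHCB2.2 15.7% against 60.5%, AT5G56710 1 of 87 against 33 of 77, FBA2 5.33% against 30.7%, and LHCB6 16.4% against 45.8%. Likewise CAB1 had 12 of 159 against 29 of 95, CAB3 8.73% against 30.1%, LHB1B2 (AT2G34420) 25 of 228 against 18 of 59, emb2171 8.25% against 23.3% and RCA 22 of 118 against 54 of 174. The 2 genes with the higher share were PSAK (AT1G30380), a photosystem I subunit, with 21.4% (21 of 98) against 0 of 50, which allows up to 6%, and AT3G09200, with 14 of 65 against 8 of 53 and an interval that included 0. Against WT, 8 genes had an interval below 0, with LHCB2.2 (15.7% against 44.7%), PSAG (2.06% against 19.6%) and AT2G45180 (3.13% against 18.2%) farthest from no change, and CRD1 was the 1 gene above (29.5% against 11.8%). With tails of 25 A or fewer no gene was left above WT or above xrn4. CRD1 had 51 tails in WT and PSAK 50 in xrn4, so this setting could drop them below the minimum of 50. Their loss there does not show that the results fail.

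Against urt1, 46 of 58 genes had the higher share in the double mutant, 11 the lower, and the interval lay above 0 for 14 and below 0 for none. CAB2 (AT1G29920) had 30.4% against 8.39%, AT3G09200 21.5% against 3.18%, PSAK 21.4% against 5.62%, and the tonoplast intrinsic protein TIP2 (AT3G26520) 26.4% against 11.8%. CRD1 had 29.5% against 16.7%, LHCB2.2 15.7% against 6.36%, LHCB6 16.4% against 8.45%, AT4G05070 (wound-responsive family) 21.9% against 10.5%, emb2171 8.25% against 2.92%, and AT3G60245 (a zinc-binding ribosomal protein) 6.47% against 0 of 174, which allows up to 1.72%. Random assignment of sets of identical reads gave 11.9 genes with an interval on either side of 0 on average for this pair and at most 21. The count of 14 is thus not beyond what these draws gave. The draws did not count the 2 sides apart, so 14 above 0 and none below was not set against chance. For the double mutant against xrn4 the draws gave 5.36 on either side on average and at most 13, against 13 observed. Against WT they gave 4.95 and at most 11, against 9 observed.

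By length, uridylation in the double mutant was highest at 11 A (25.6%; exact 22.9 to 28.4) and was 22.2% for tails of 4 to 9 A, against 12.8% in urt1 and 49.5% in xrn4. Tails with 1 U made up 52.6% of its uridylated tails (49.8 to 55.6) and tails with 3 or more U 18.4% (16.2 to 20.7), each between urt1 and xrn4. Extensions with U and A made up 26.8%. The share of tails under 10 A was 24.7% (23.4 to 26), 4.96 points above urt1 (3.25 to 6.59) and -2.05 points from xrn4 (-4.33 to 0.256). Relative to the single mutants, the share of uridylated tails departed from additivity on the log2 scale by 0.62 (0.43 to 0.80), while on the linear scale the departure was -1.99 points (-5.25 to 1.38). Mean A length was longer than in urt1 for 91 of 203 genes and shorter for 112 (median -0.18 nt, quartiles -1.48 and 0.84). Among the 25 genes with at least 100 tails in each, CAB1 (-2.98 nt), AT4G05070 (-2.91), LHB1B2 (-2.12), CRD1 (-1.52) and CAB3 (-1.47) had the largest decreases, and GER1 (AT1G72610; 1.17 nt) and LHCB2.1 (0.76) the largest increases.

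Ribosomal protein transcripts had 6.71% uridylated tails in the double mutant against 38.7% in xrn4 and 3.27% in urt1, photosystem transcripts 11.5% against 30.9% and 7.44%, and Calvin cycle transcripts 9.24% against 20.3% and 10%. The Calvin cycle difference from urt1 of -0.787 points over members read in both lay at percentile 2 of random lists, but RCA alone set its sign: without RCA, left out after the data were examined, the shares were 7.82% and 6.88%. In share of reads, Calvin cycle members were below xrn4 with a median log2 ratio of -0.72 over 11 members (0 higher, 2 lower), at percentile 2.08 of random lists, and RCA had 118 reads (4487 CPM) against 174 (17761 CPM) in xrn4 (log2 ratio -1.98, -2.33 to -1.64). With the members of at least 50 reads alone the percentile was 4.22. Ribosomal protein members had medians of 0.92 over WT (16 tested, 7 higher, 2 lower; percentile 94.5), 0.37 over xrn4 (18 tested, 5 higher, 4 lower) and -0.29 over urt1 (24 tested, 3 higher, 4 lower). Photosystem members had 0.10 (36 tested, 4 higher, 1 lower), 0.12 (37 tested, 7 higher, 2 lower) and -0.01 (41 tested, 2 higher, 1 lower). The first 2 were 0.65 (10 higher, 0 lower) and 0.50 (10 higher, 1 lower) with TMM scaling, and turned negative with median of ratios scaling. The Calvin cycle medians were 0.04 over WT (12 tested, 0 higher, 3 lower), which also turned, and -0.42 over urt1 (15 tested, 0 higher, 4 lower). The sign turned with identical reads counted once for all 3 photosystem medians, for the Calvin cycle medians over WT and urt1 and for the ribosomal protein medians over xrn4 and urt1. Such counting also merges different molecules with the same A length and extension, more so in the deeper library. These turns therefore cannot be put down to copies alone.

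In the double mutant 85 genes were higher and 32 lower than in WT, 88 and 49 relative to xrn4, and 73 and 61 relative to urt1. PSBR (AT1G79040), a photosystem II subunit, had 327 reads against 20 in WT (log2 ratio 2.65, 2.03 to 3.41) and 17 in xrn4 (2.80, 2.14 to 3.64). The glycine-rich protein gene GRP23 (AT2G32690, 47 reads) was at least 6.14-fold above WT and had a log2 ratio of 2.25 over urt1 (1.43 to 3.19). CP12-1 (3.59, 2.22 to 6.10), XTH4 (70 reads against 1, log2 interval 2.25 to 10.10), TCTP (AT3G16640; 3.47, 1.48 to 9.38) and AT1G13360 (2.94, 1.54 to 5.46) were also above WT, as was the lipid transfer protein gene LTP5 (AT3G51600), at least 4.31-fold. RCA (-1.91), GLDP1 (AT4G33010, glycine decarboxylase; -2.44), GLU1 (AT5G04140; -2.57), GAPC2 (AT1G13440; -1.96) and GSTU20 (-2.01) were below WT. Relative to xrn4, RPS15A (3.03) and PSRP6 (AT5G17870, a plastid ribosomal protein; 3.13, 1.75 to 5.66) were higher, and KUF1 (-5.57, -11.48 to -3.52), the peroxisomal malate dehydrogenase PMDH2 (AT5G09660; -4.31, -7.75 to -2.53), MS2 (-3.09) and ERF1-1 (-4.17, -6.74 to -2.64) lower. Relative to urt1, RAP2.4 (AT1G78080, 24 reads against 1; 4.75, 2.69 to 10.7), BBX15 (AT1G25440; 3.04) and RALF23 (AT3G16570; 2.84) were higher, and RPL24A (AT2G36620; -2.29), GAPC2 (-1.70), RP1 (AT1G43170, ribosomal protein L3; -1.70), ATMS1 (AT5G17920; -1.64), PFL (-1.61) and LOS1 (AT1G56070, elongation factor 2; -1.61) lower. CXE18 (AT5G23530) was at least 12.1-fold above urt1, but its 22 reads shared 1 end. Random assignment of sets of identical reads gave 63.5, 75.4 and 99.8 genes on average for the 3 pairs and at most 82, 96 and 123, against 117, 137 and 134 observed. Counting identical reads once left 5 higher and 11 lower, 8 and 10, and 10 and 3. TMM scaling turned the split against urt1 to 53 higher and 85 lower, and median of ratios scaling turned the splits against WT and xrn4 to 54 and 61, and 60 and 64.

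G extensions and C extensions were each less frequent than U extensions in every library, for G by a small margin in urt1. G extensions made up 4.93% of tails in WT (4.15 to 5.74), 5.94% in urt1 (5.44 to 6.48), 5.59% in xrn4 (4.74 to 6.49) and 1579 of 26300 tails in urt1 xrn4 (5.41 to 6.64), and C extensions 2.41%, 2.05%, 3.27% and 2.16%. The G share did not differ detectably between urt1 xrn4 and urt1 (two-sided Fisher's exact test on the reads of these libraries, not the genotypes, p = 0.729), nor did the C share (p = 0.312), while the U share did (p = 3.89e-174). This test covers counting error only and treats repeated reads as independent. With genes resampled, the interval excluded 0 for G in urt1 minus WT (1.01 points, 0.0315 to 1.97) and urt1 xrn4 minus WT (1.07, 0.116 to 2.07), and for C in xrn4 minus WT (0.859, 0.258 to 1.53) and urt1 xrn4 minus xrn4 (-1.10, -1.76 to -0.464). It included 0 in the other comparisons of G and C. The U share in urt1 was close to the G share of the same library. The other gene lists held few reads: 33 over all libraries for the uridylation and decay factors (14 of 26 members read), 36 for poly(A) binding proteins (3 of 8), 190 for miRNA targets (24 of 57), 119 for ethylene signalling (6 of 6), 122 for heat shock (2 of 9), 22 for touch and wound response (5 of 10), 9 for the circadian clock (4 of 12) and 32 for root markers (4 of 9). Salicylic acid defence, seed storage and floral identity genes had 0 reads. In these lists single genes stood out only by name: EBF1 had 91.3% uridylated tails in WT (23 reads, 8 distinct ends), 32.1% in urt1 (28 reads), 0 of 3 in xrn4 and 22 of 40 in urt1 xrn4. HSC70-1 (AT5G02500), a cytosolic chaperone, had 63.2% in WT (19 reads), 13.8% in urt1 (58), 46.2% in xrn4 (13) and 28.6% in urt1 xrn4 (28).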

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

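The test of length with the added nucleotides counted was chosen after the result was seen, and the other tests in this part before their own results were seen. The effect of 1 mutation was compared between the 2 backgrounds of the other mutation, and 4 measures had effects of opposite sign with read-based intervals that excluded 0. With 1 library per genotype these differences were not tested against replicates. Read-based intervals are too narrow: with genes resampled, the interval included 0 for tails under 10 A in urt1 xrn4 against xrn4 (-4.33 to 0.256) and for extensions of U only in urt1 xrn4 against urt1 (-1.13 to 6.16) and, with signs exchanged, of U and A. The share of tails under 10 A was higher in urt1 than in WT by 1.78 points and lower in urt1 xrn4 than in xrn4 (-2.05 points), a difference of -3.83 points. The share of uridylated tails with 2 U was lower in xrn4 than in WT (-5.76 points) and higher in urt1 xrn4 than in urt1 (7.01 points), a difference of 12.8 points. Extensions of U only differed by -4.60 points between xrn4 and WT and by 2.46 points between urt1 xrn4 and urt1, a difference of 7.06 points. Extensions of U and A are the remainder, with 4.60 and -2.46 points and a difference of -7.06 points.

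For the share of tails under 10 A, 3 technical explanations were set against an effect of URT1 that depends on XRN4. Copies of the same molecule did not account for it, since the difference was -4.02 points (-5.97 to -2.16) with identical reads counted once. Different genes in the libraries stay open, since within 718 genes it was -2.65 points (-5.40 to 0.0195). The way length is measured fits: with the added nucleotides counted as tail, both effects were positive (4.34 and 2.92 points) and their difference was -1.42 points (-3.74 to 0.926), so the opposite signs may come from U standing where A is not counted. An effect of genotype was not tested, because each genotype has 1 library.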

How the results depend on the processing

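Over 71 results and 349 alternatives, 235 alternatives kept the result within a tolerance set for its kind. Of the others, 110 moved it beyond that, 2 made a list stand further apart, 1 less far, and 1 reversed it. The tolerance is wide for gene counts. With median of ratios scaling, the 88 higher and 49 lower genes of urt1 xrn4 against xrn4 became 60 and 64, within tolerance. Lists were judged by percentile. The photosystem median of urt1 against WT turned from 0.15 to -0.10 with that scaling, also within tolerance. Of the 235, 39 could not have moved by construction: tails with at least 1 A and no organelle genes removed no read (8), rescaling shifts all genes alike and leaves list percentiles in place (30), and WT has its own tail lengths (1). That leaves 196 of 310. Using either lane alone moved no share of uridylated tails. A class boundary of 30 A was not run, since no tail is longer. The order of the 4 libraries in the share of uridylated tails was the same in every setting printed here. The depth of the smallest library, 9797 reads, limits how many genes can be compared. The cause of a move was not tested unless given. Values follow the order WT, urt1, xrn4, urt1 xrn4 unless stated. Counting identical reads once was chosen after the data were examined. It also merges different molecules of a gene with the same A length and extension, more so in genes with many reads and in deeper libraries.

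Share of uridylated tails: with 2 or more U required, 21.3, 2.11, 30.4 and 6.34%; with identical reads counted once, 28.4, 10.4, 31.2 and 16.7%; as a mean over genes with at least 20 tails, 23.6% in WT, 5.66% in urt1 and 9.98% in urt1 xrn4. Without the 20 genes with the most tails it was 33.6% in WT and 41.9% in xrn4. At the tail lengths of WT it was 6.59% in urt1, 35.3% in xrn4 and 12.2% in urt1 xrn4. The difference between shortest and longest tails was 12.1, 6.10, 16.2 and 11.1 points with added nucleotides counted in the length, and 7.26 in urt1 and 15.2 in urt1 xrn4 with classes split at 15 A. Tails with 1 U, with identical reads counted once, were 39.1% in WT, 72.1% in urt1 and 33.6% in xrn4. Tails under 10 A were 18.8, 20.8, 28.0 and 25.7% without the 20 genes with the most tails, and 13.8, 16.5, 22.0 and 19.1% as a mean over genes. With identical reads counted once they were 23.1% in xrn4 and 21.0% in urt1 xrn4. Tails over 25 A were 6.47% in WT without those 20 genes, and with the boundary at 20 A they were 20.04, 16.4, 12.6 and 15.5%.

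Genes with an interval of the uridylation difference on 1 side of 0 were counted in a fixed order. The order is urt1 lower than WT, xrn4 higher than WT, urt1 xrn4 lower than WT, lower than xrn4 and higher than urt1. With a minimum of 20 tails the counts were 33, 14, 25, 30 and 38, of 58, 34, 53, 47 and 203 genes tested. With 100 tails they were 3, 1, 4, 3 and 8, of 4, 3, 4, 3 and 25 genes tested. With identical reads counted once they were 0, 0, 0, 0 and 0, where 2, 1, 0, 0 and 2 genes had enough tails left. In the other direction, a minimum of 20 tails gave 4 genes lower in xrn4 than in WT and 2 lower in urt1 xrn4 than in urt1. The 1 gene higher in urt1 xrn4 than in WT and the 1 higher than in xrn4 became 0 and 0 with 100 tails, with tails of 25 A or fewer, and with identical reads counted once. These genes, CRD1 and PSAK, had too few tails to be tested in the first and last of these settings. With tails of 25 A or fewer they could fall below the minimum of tails. These counts therefore do not show that their results fail.

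Genes with a higher and a lower share of reads are given where the count moved beyond its tolerance. The order is urt1 against WT, xrn4 against WT, urt1 xrn4 against WT, against xrn4 and against urt1. With TMM scaling: 199 and 10 for urt1 against WT; 139 and 17 for urt1 xrn4 against WT; 28 lower for urt1 xrn4 against xrn4. With median of ratios scaling: 56 lower in urt1 than in WT; 54 and 61 for urt1 xrn4 against WT. With no minimum: 490 lower; 226 and 177; 159 and 503; 153 and 427; 575 and 237. With at least 50 reads, where fewer genes are tested: 42 and 6; 0 and 2; 21 and 10; 25 and 10; 15 and 26. With a ratio of at least 3: 15 higher in xrn4 than in WT, 18 lower in urt1 xrn4 than in WT, 26 lower than in xrn4, and 35 higher and 33 lower than in urt1. Thinned to the shallower library: 27 and 14 for urt1 against WT; 25 higher in urt1 xrn4 than in WT; 31 and 20 against xrn4. With identical reads counted once: 10 and 17; 3 and 2; 5 and 11; 8 and 10; 10 and 3.

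The percentile of the share of reads among random lists was 1.92 in place of 28.7 for Calvin cycle genes of urt1 xrn4 against WT with members of at least 50 reads, and 4.22 in place of 2.08 against xrn4. For ribosomal protein genes of urt1 xrn4 against WT it was 99.9 with identical reads counted once, in place of 94.5. With members of at least 50 reads it was 70.0, with a median of 0.58 over 5 members (2 higher, 2 lower). List medians changed sign with members of at least 50 reads for ribosomal protein genes in xrn4 against WT (-0.22) and urt1 xrn4 against xrn4 (-0.34), and in urt1 xrn4 against WT for photosystem (-0.08) and Calvin cycle genes (-0.85). With identical reads counted once they changed for photosystem genes in all 5 comparisons (-0.38, 0.13, -0.23, -0.35 and 0.21), for Calvin cycle genes in urt1 against WT (-0.63) and urt1 xrn4 against WT (-0.77) and urt1 (0.17), and for ribosomal protein genes in urt1 xrn4 against xrn4 (-0.10) and urt1 (0.12). With each member left out in turn, the sign of the pooled uridylation difference turned only for Calvin cycle genes, in xrn4 against WT without FBA1 (2.19 points) and in urt1 xrn4 against urt1 without RCA (0.936 points). The departure from additivity of the uridylated share had the opposite sign on the linear scale (-1.99 points) from the log2 scale (0.62), which the change of scale itself brings about.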

Other observations

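G extensions varied between genes as widely as U extensions in urt1. Over the 58 genes with at least 50 tails in urt1 and urt1 xrn4, the G share in urt1 ran from 0 to 28.5% and the U share from 0 to 25.7%. In WT, the uridylated tails had a median of 13 A and in urt1 xrn4 of 11 A. FBA1, the aldolase, had 22 of 38 tails uridylated in WT, 20 of 222 in urt1, 5 of 45 in xrn4 and 19 of 134 in urt1 xrn4. The ribosomal protein gene emb2386 (AT1G02780) had 16 of 49, 3 of 115, 21 of 40 and 1 of 42. TIR1 (AT3G62980), a miRNA target, had 0 of 1 tails uridylated in WT, 0 of 2 in urt1, 6 of 6 in xrn4 and 5 of 5 in urt1 xrn4, too few to compare.

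In this part the tests of leaking reads and of G and C extensions were chosen after the result was seen. Uridylated tails remained in urt1 and were more frequent in urt1 xrn4, and 3 technical sources were weighed against a second uridylyltransferase such as HESO1. A genome-encoded A run followed by T was found in the own gene of 0.442% of 1358 U-only tails of 10 A or more (0.295% in shuffled genes), which rules it out for those tails, while for all lengths 17.37% of 2101 tails matched against 15.4% by chance. A single base-calling error rate could not account for them, since the U share per gene in the 2 libraries was correlated (Spearman rho 0.696 over 58 genes, shuffled -0.262 to 0.260; 0.453 for tails of 10 A or more), and the ratio of G and C shares in urt1 xrn4 over urt1 was 1.02 (0.914 to 1.15) where that of U was 1.95 (1.76 to 2.13); G and C shares were correlated as well (rho 0.402 and 0.294, and 0.278 and 0.389 for tails of 10 A or more), so a background that depends on the gene could still add to the U share. In urt1 8.68% (6.99 to 10.6) of uridylated tails had 3 or more U against 21.2% in WT. Leakage of WT or xrn4 reads could therefore not be the whole cause there. In urt1 xrn4 this share was 18.4% (16.2 to 20.7), and 52.6% of its uridylated tails held 1 U (49.8 to 55.6). The share with 1 U was 32.8% in WT and 24.5% in xrn4, so leakage could not be the source of all these tails. These shares cover all uridylated tails and not the excess over urt1 alone, so leakage stays open for that excess. A second enzyme was not tested, since no HESO1 mutant is part of the series.

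Tails with 3 or more U were more frequent without XRN4, and 3 technical explanations were weighed against an effect of genotype. Copies of the same molecule did not account for it: with identical reads counted once xrn4 exceeded WT by 10.5 points (6.72 to 14.3) and urt1 xrn4 exceeded urt1 by 10.1 (7.66 to 12.4). Nor did different genes, with 15.6 points (10.3 to 20.4; 244 genes) and 7.65 points (4.36 to 10.7; 356 genes) within genes. Nor did shorter A tracts, with 10.4 points (6.36 to 14.8) and 8.84 points (6.04 to 11.7) at equal A lengths. The biological explanation, that long U extensions accumulate where XRN4 is missing, is left standing by these tests but may also be a difference between single libraries, since 10.5 points were measured without a replicate.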
